A study of Mus musculus with 20 samples.

How the data were processed

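RNA of bone marrow VE-cadherin+ endothelial cells from adult C57/Bl6 mice was profiled on 20 Affymetrix arrays, 5 each for non-irradiated mice and for 6 hours, 24 hours and 14 days after 5 Gy of total body irradiation. Per the labels' protocols, RNA was extracted with the Qiagen RNeasy micro kit, amplified with the NuGEN Ovation RNA Amplification System V2 and labelled with biotin. The deposited values are linear probe set intensities, 1 column per array, which the authors had scaled so that the mean of an array's probe sets, after trimming 2% at each end, is 500, as read from the values. The submitters' processing notes name Affymetrix Expression Console and Transcriptome Analysis Console, with no versions. No summarization algorithm, background correction or filter is given in the sources used here. The number of arrays limits the precision.

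Of the probe sets 34945 carried 1 gene symbol in the platform's annotation, 932 carried several, 9160 were unnamed here, and 64 were controls. An update of symbols through the reference gene table (assembly GRCm38.p6, used for names only) changed 0 symbols, and 34741 probe sets matched it by gene number. Values were log2 transformed after adding 1. Each gene was represented by its probe set with the highest mean over all 20 arrays, which left 18193 genes, with no filter on dim genes. Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in a single model of the 4 groups on all 20 arrays. Calls used a two-sided Benjamini-Hochberg adjusted p under 0.05 over all genes. The 3 irradiated groups were compared with the non-irradiated group and with each other, and an F test took all 4 groups together. Mean signals are given with the SD over 5 arrays, log2 changes with limma's standard error. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

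Gene lists (34, with 620 distinct members) were tested with limma's camera at a preset correlation of 0.01, adjusted over 102 tests (34 lists at 3 times), and the 102 tests of the direct contrasts were adjusted as a family of their own. Members are counted past the threshold over all genes and adjusted over the list alone. The error of a list's mean is the standard error of the difference between 5 and 5 arrays of the members' mean. Camera with an estimated correlation and fry were run as alternatives. Fry tests whether a list's genes move on balance in 1 direction and does not compare the list with other genes. Members without a probe set of their own name here were left out of the counts. Named genes followed a rule with 3 parts. For each time, these were the 6 largest fitted rises and 6 largest fitted falls among called genes whose 5 irradiated arrays all lay on 1 side of all 5 non-irradiated arrays, leaving out predicted and clone symbols. From each list came up to 3 called members with the largest absolute change, or the member with the smallest p where fewer than 2 passed. Cdkn1a, Mdm2, Mki67, Cdh5, Pecam1, Ptprc, Kitl and Cxcl12 were always included. For each direct contrast the 4 largest fitted rises and 4 such falls were taken. A gene under more than 1 part counted under each.

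The background of an array was set to the 95th percentile of its 27 probe sets for bacterial genes absent from the sample, from 17.5 to 51.5 over the arrays. Where every array of a group lay at or under it, the change is given as a lower bound against that level. This level was chosen after seeing the data. Comparisons that share the non-irradiated arrays were set beside 50 simulations of unchanged groups, the count expected of independent lists, and fits with the controls split 2 and 3. The model, lists, tests and naming rule were chosen before the data were examined. So were most of the other settings tried: quantile normalization, centring each array on its median, leaving out genes below the 40th percentile of mean signal, the mean of a gene's probe sets, every probe set, leaving out probe sets open to cross-hybridization, adding 16 in place of 1, no intensity trend, array weights, only the 2 groups compared, an adjusted p under 0.01, a 2-fold minimum, the replicate number as a block, covariates for the 3' minus 5' signal and the pan-leukocyte mean, and leaving out each array in turn. The erythroid mean as a covariate was added after seeing the data, as were the addition of 16 for lists and named genes and median centring for named genes. Probe sets with no single gene name entered array medians, quantile normalization, every-probe-set counts and the closing section.

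The model was tested on data simulated for 6 hours against non-irradiated, with 18193 genes, real means and spreads and 200 changed genes. It recovered 16.4%, 34.3% and 66.7% of genes changed 1.5-fold, 2-fold and 4-fold, and 26.8%, 59.5% and 93.3% of those above the median signal. Of 87 calls 9 were false. With no effect the median of 10 runs was 0 calls. In simulated arrays camera called the list of 30 changed genes and 1 of 100 random lists. Real arrays regrouped at random called up to 26 lists, so this is no general rate.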

Results

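Gene expression was measured on 20 single-colour Affymetrix arrays, each hybridized with amplified total RNA of bone marrow cells from adult C57/Bl6 mice that the labels call VE-cadherin+ endothelial cells. VE-cadherin, the product of Cdh5, is an adhesion protein of endothelial cell junctions. There were 4 groups of 5 arrays: non-irradiated mice, and mice 6 hours, 24 hours and 14 days after 5 Gy of total body irradiation. The labels call the 5 arrays of a group biological replicates and do not say whether each is 1 animal or a pool. The p-values rest on the spread between these samples, pooled over the 4 groups. Array pairs differed more at 6 hours (median absolute log2 difference 0.611 to 0.676) than elsewhere (0.285 to 0.419), so p-values there may be too small. After collapse to 1 probe set per gene, 18193 genes were compared. Changes are log2 fold changes ± SE, and adjusted p-values come from limma. A range after an adjusted p runs over all alternatives tried for that result, fry included for lists.

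The median correlation across genes between arrays of a group was 0.939 in the non-irradiated group, 0.898 at 6 hours, 0.954 at 24 hours and 0.959 at day 14, against 0.903 between groups, so those at 6 hours resembled each other no more than arrays of different groups. Genes are not independent replicates in these values. The arrays' own controls set the 24-hour and day 14 groups apart from the other groups. The bacterial hybridization controls had a mean log2 signal of 12.99 ± 0.063 (SD, n = 5) in the non-irradiated group and 13.08 ± 0.15 at 6 hours, but 12.42 ± 0.12 at 24 hours and 12.35 ± 0.16 at day 14. The 3' minus 5' log2 signal of Gapdh was 1.33 ± 0.040, 1.58 ± 0.29, 0.77 ± 0.056 and 0.89 ± 0.12 in the same order. The median signal of an array went from 177 ± 10.1 in the non-irradiated group over 149 ± 9.23 and 135 ± 5.18 to 94.5 ± 8.38 at day 14, while the trimmed mean was fixed by the deposited scaling.

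The first comparison asked how cells differed from non-irradiated ones at 6 hours. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, rose from 943 ± 66.8 to 5970 ± 416 (mean signal ± SD, n = 5 per group). Its log2 change was 2.66 ± 0.096 (adjusted p = 2.74e-16). Genes of the cell cycle and of red cell precursors fell in the same arrays, and endothelial markers rose. Cdh5 itself rose from 3190 ± 494 to 8950 ± 1260 (1.49 ± 0.12). Mki67, a marker of cycling cells, went from 18100 ± 367 to 8870 ± 844 (-1.03 ± 0.077). In total 2343 genes rose and 2640 fell, 27.4% of those tested, and 1139 and 1419 did so by at least 2-fold. With arrays centred on their medians the split was 3532 and 1617.

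Among genes whose 5 irradiated arrays lay above all 5 non-irradiated arrays Fgf23, a hormone of phosphate balance, went from 25.1 ± 12.9 to 2580 ± 775 (log2 change 6.84 ± 0.42; adjusted p = 3.31e-12), or 6.34 without non-irradiated replicate 4, which read lowest. Zfp365 rose by 5.43 ± 0.86 at an uneven signal of 1140 ± 1300, with another probe set at 2.18, and Eda2r, a p53-induced receptor of the tumour necrosis factor family, by 5.10 ± 0.48. Edn1, the precursor of the vasoconstrictor endothelin, rose by 4.63 ± 0.37 and the semaphorin Sema3f by 4.52 ± 0.60 (another probe set 1.76). Igkv6-14 read 4.43 ± 0.37, a value that is uncertain because immunoglobulin variable genes form a family of similar sequences. Falls named by their fitted change were those of Fn3k (at least 13.3-fold lower), Tac2 (at least 19.8-fold), Aldh1a7 (at least 28.7-fold), Redrum (at least 3.71-fold), Btnl10 (-6.30 ± 0.53) and the red cell antigen gene Rhd (-5.85 ± 0.55), where a lower bound stands for a group at the array's background and gives no rank. The lower mean of Fgf23, Zfp365, Sema3f, Btnl10, Bmx and Rhag lay under its group's mean background with an array above it, so their fitted changes are no exact sizes.

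Targets of p53 rose and genes of proliferation fell. Of 38 measured p53 target genes 28 rose and 0 fell (29 and 0 adjusted over the list alone), with a median log2 change of 1.20 and a mean of 1.45 ± 0.066 (camera adjusted p = 6.11e-21). Dcxr rose by 3.58 ± 0.23 and Dglucy by 3.48 ± 0.33, and Mdm2, the ligase that degrades p53, rose by 1.00 ± 0.12 (another probe set 0.31). All 29 measured mitosis genes fell (29 over the list alone; median -1.69, adjusted p = 2.15e-23), among them the survivin gene Birc5 (-2.59 ± 0.14) and the kinetochore gene Ndc80 (-2.96 ± 0.61). DNA replication genes fell in 31 of 31 cases (31 over the list alone), with a median of -1.76 and adjusted p = 7.89e-31. The origin licensing gene Cdc6 fell from 3400 ± 82.3 to 312 ± 88.1 (-3.48 ± 0.16). Of 20 measured homologous recombination and Fanconi genes 0 rose and 18 fell (0 and 18 over the list alone), with Bard1 at -3.69 ± 0.46 and Palb2 at -2.85 ± 0.39 (median -1.47, adjusted p = 1.11e-09). In these arrays the erythroid list's mean change was -2.55 ± 0.15 and the pan-leukocyte list's -0.34 ± 0.046.

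Inflammatory genes rose. Of 26 measured NF-kB and cytokine genes 19 rose and 1 fell (19 and 1 over the list alone), at a median of 1.09 (adjusted p = 1.07e-14). The monocyte chemokine Ccl2 rose from 1040 ± 367 to 15000 ± 2060 (3.90 ± 0.17) and the leukocyte adhesion gene Selp by 3.12 ± 0.21. Of 26 measured interferon-stimulated genes 14 rose and 1 fell (16 and 1 over the list alone), with a median of 0.73 and adjusted p = 7.19e-06, Ifit1 at 2.37 ± 0.22 and Cmpk2 at -1.66 ± 0.30. Of 16 measured senescence and secretory genes 7 rose and 1 fell (7 and 2 over the list alone), the cytokine Il6 by 2.65 ± 0.28 (median 0.23, adjusted p = 0.000166). Of 14 measured NRF2 and antioxidant genes 2 rose and 7 fell (2 and 8 over the list alone), at a median of -0.25 (0.0030 with arrays centred on their medians). Adjusted p was 0.0168, and 0.0682 with an estimated correlation (range 4.21e-08 to 0.244). The glutathione synthesis genes Gclm (-1.91 ± 0.13; another probe set -0.82) and Gclc (-1.78 ± 0.19) were among those that fell.

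Endothelial lists rose. Of 29 measured pan-endothelial markers 26 rose and 0 fell (26 and 0 over the list alone), with a median of 1.42 and a mean of 1.36 ± 0.031 (adjusted p = 1.87e-24). Plvap, a protein of endothelial fenestrae, rose by 2.50 ± 0.17, Robo4 by 2.08 ± 0.14 and Pecam1 by 1.42 ± 0.18, or 0.57 with the pan-leukocyte covariate (adjusted p = 0.511, range 2.38e-08 to 0.511). Of 14 measured sinusoidal endothelial markers 13 rose and 1 fell (13 and 1 over the list alone) (median 1.75, adjusted p = 2.23e-18), the scavenger receptor Stab1 by 3.06 ± 0.19. Of 18 measured arterial and arteriolar endothelial markers 9 rose and 2 fell (9 and 2 over the list alone), at a median of 0.52 (0.45 with members at background set to their bounds) and adjusted p = 0.00189, and the kinase gene Bmx fell by 3.26 on the log2 scale. Coagulation and vessel-tone genes rose in 12 of 16 cases (12 over the list alone; median 1.01, adjusted p = 1.77e-11), with the protein C receptor gene Procr at 2.59 ± 0.30. Basement membrane genes rose in 12 of 13 cases (13 alone), at a median of 0.89 and adjusted p = 9.81e-11. In the same arrays the 3' minus 5' signal and the hybridization controls lay near the non-irradiated ones.

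Signalling and stromal lists also shifted upwards. Of 18 measured TGF-beta and BMP pathway genes 14 rose and 0 fell (15 and 0 over the list alone), at a median of 0.80 (adjusted p = 6.58e-10), and the matricellular gene Ccn2 rose by 2.39 ± 0.089. Of 20 measured VEGF and sprouting genes 13 rose and 2 fell (16 and 2 over the list alone), at a median of 0.98 (adjusted p = 9.31e-09), and Apln, a peptide of sprouting vessels, by 4.39 ± 0.45. Of 25 measured semaphorin, plexin and neuropilin genes 14 rose and 1 fell (15 and 2 over the list alone), with a median of 0.51, adjusted p = 7.53e-06 and Sema3a at 2.45 ± 0.25. Of 29 measured niche and angiocrine factors 14 rose and 0 fell (15 and 2 over the list alone), with a median of 0.78 (0.64 with members at background set to their bounds) and adjusted p = 0.000834. Kitl, the stem cell factor gene, read -0.23 ± 0.099 (another probe set 0.13; adjusted p = 0.0953; 0.033 without 6-hour replicate 3, 0.0171 with quantile normalization, range 0.0171 to 0.918). Cxcl12, a chemokine that retains stem cells in the marrow, read 0.12 ± 0.088 (adjusted p = 0.382; 0.0373 when centred and 0.0106 with the mean of its probe sets, range 0.0106 to 0.937). Of 16 measured Notch pathway genes 8 rose and 2 fell (8 and 2 over the list alone) at a median of 0.58 (adjusted p = 0.0112). Of 15 measured mesenchymal transition genes 10 rose and 0 fell (11 and 1 over the list alone) at a median of 0.68 (adjusted p = 1.39e-06). Of 18 measured stromal and osteoblast markers 12 rose and 0 fell (13 and 0 over the list alone) at a median of 0.46 (adjusted p = 1.05e-06).

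Markers of other bone marrow cells moved in both directions. Of 13 measured erythroid markers 0 rose and 12 fell (0 and 12 over the list alone), with a median of -2.58 and a mean of -2.55 ± 0.15 (adjusted p = 2.91e-17). Klf1, the master regulator of red cell genes, went from 5690 ± 288 to 430 ± 174 (-3.83 ± 0.23) and the blood group gene Rhag fell by 5.06 on the log2 scale. Of 14 measured granulocyte markers 0 rose and 12 fell (0 and 13 over the list alone) at a median of -0.53 (adjusted p = 1.82e-09), and lactoferrin, Ltf, read -1.53 ± 0.14. Of 17 measured monocyte and macrophage markers 0 rose and 8 fell (0 and 10 over the list alone) at -1.07 (-0.79 with members at background set to their bounds) (adjusted p = 8.95e-05). Of 15 measured pan-leukocyte markers 2 rose and 7 fell (2 and 7 over the list alone) at -0.34 (adjusted p = 0.003), including Ptprc, which encodes the leukocyte antigen CD45, at -0.83 ± 0.11. Megakaryocyte markers rose in 9 and fell in 3 of 12 cases (the same counts over the list alone; median 1.40, adjusted p = 3.09e-05), with Clec1b at 2.22 ± 0.23 and Gata1 at -1.97 ± 0.21. Of 6 measured mast cell and basophil markers 3 rose and 1 fell (3 and 1 over the list alone) at 0.97 (adjusted p = 0.0112).

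The set test called 26 of the 34 lists at 6 hours, 25 of them also with an estimated correlation, and the NRF2 list was the exception. The 8 others did not pass. Non-homologous end joining genes had 1 higher and 3 lower of 10 (the same over the list alone), at a median of -0.56 (adjusted p = 0.378). Apoptosis genes had 9 higher and 5 lower of 18 (9 and 6 over the list alone), at a median of 0.62 (adjusted p = 0.102). Sterol biosynthesis genes had 1 higher and 3 lower of 16 (the same over the list alone), at a median of -0.29 (adjusted p = 0.333). Glycolysis genes had 4 higher and 3 lower of 13 (5 and 3 over the list alone), at a median of 0.24 (adjusted p = 0.199). Control genes had 2 higher and 4 lower of 7 (the same over the list alone), at a median of -0.40 (adjusted p = 0.378). B-lineage markers had 2 higher and 3 lower of 15 (2 and 4 over the list alone), at a median of -0.80 (adjusted p = 0.199). T and NK cell markers had 4 higher and 0 lower of 14 (the same over the list alone), at a median of 0.18 (adjusted p = 0.254). Stem and progenitor cell markers had 4 higher and 3 lower of 13 (4 and 4 over the list alone), at a median of -0.080, above 0 when centred (adjusted p = 0.78). That list had a mean of 0.019 and an upward test beside its negative median. Some alternatives took lists past the threshold. The adjusted p of the apoptosis list was 0.0416 when centred (range 1.11e-07 to 0.816), that of the glycolysis list 0.0403 with the pan-leukocyte covariate (range 0.00048 to 0.677) and that of the B-lineage list 0.0452 with the mean of a gene's probe sets (range 0.00723 to 0.931).

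With the pan-leukocyte mean as a covariate 509 genes were higher and 525 lower at 6 hours, and with the erythroid mean 47 and 95. Of the variance of these 2 means 84.3% and 99% lay between the groups. With the pan-leukocyte covariate, adjusted p was 0.0856 for the arterial list (range 1.39e-09 to 0.337), 0.266 for the Notch list (2.37e-07 to 0.832) and 0.52 for the pan-leukocyte list (1.41e-09 to 0.52), which read 0.0552 with arrays centred on their medians. With the erythroid covariate 35 of 102 list shifts were called, against 61 without it.

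**Figure D1:**
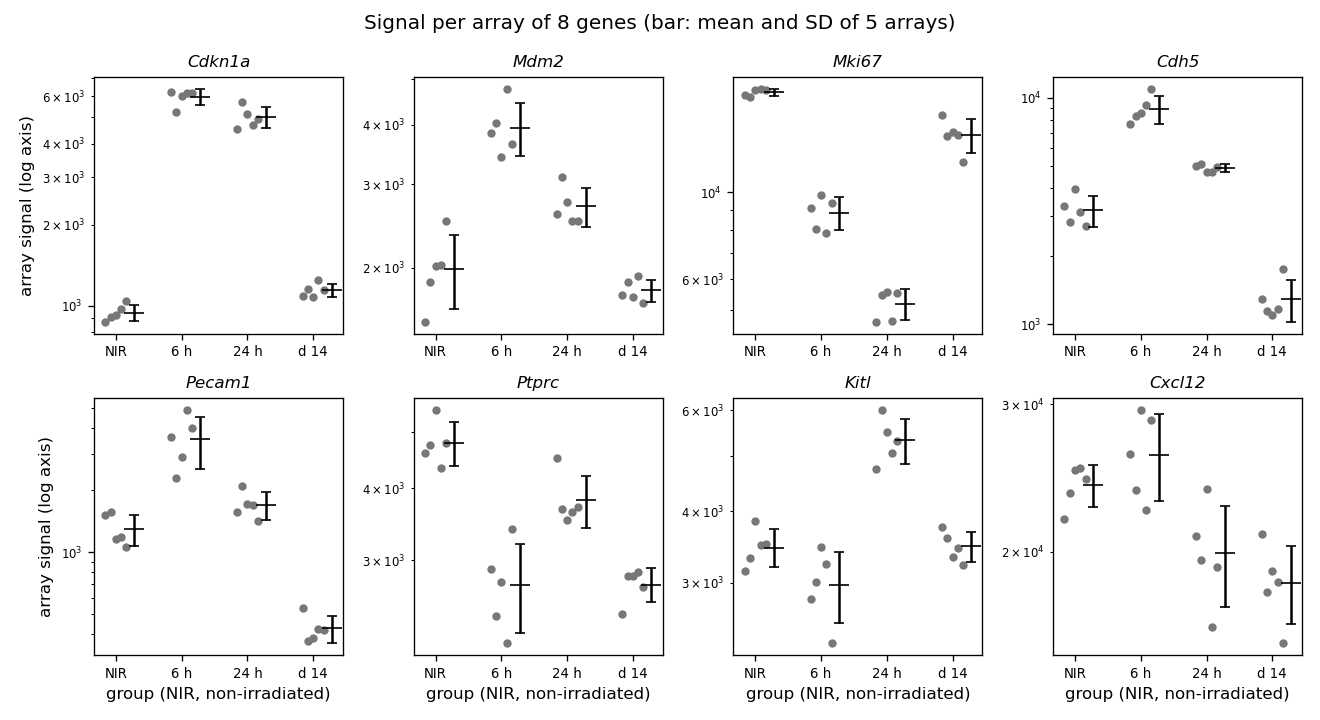
Signal per array (log axis, arbitrary units) of 8 genes named beforehand in the non-irradiated group (NIR) and at 6 hours, 24 hours and day 14, with points for the 5 arrays and bars for mean and SD. Cdkn1a had a mean of 943 in the non-irradiated group, 5970 at 6 hours, 5020 at 24 hours and 1140 at day 14, and Cdh5 3190, 8950, 4890 and 1290.

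The comparison at 24 hours asked the same. Acta2, the smooth muscle actin gene, rose from 195 ± 79.3 to 7640 ± 511 (mean signal ± SD, n = 5 per group; log2 change 5.36 ± 0.28, adjusted p = 8.56e-14) on the brightest of its 3 probe sets, which read 0.66 to 5.36. The interferon-induced Ifit1 rose from 347 ± 156 to 6300 ± 355 (4.30 ± 0.22). Cdkn1a stood at 2.41 ± 0.096 and Mki67 at -1.80 ± 0.077. Kel, a red cell antigen gene, changed by -7.48 ± 0.52, or -6.69 without 24-hour replicate 4. In all 2861 genes rose and 2513 fell (29.5%), 1464 and 1338 of them by at least 2-fold, and the split was 4950 and 1139 with arrays centred on their medians.

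Among genes named by their fitted change, Actg2, another smooth muscle actin, was at least 8.68-fold higher and the antiviral Mx2 at least 5.13-fold higher, while Zfp365 rose by 4.88 ± 0.86 (another probe set 0.94) and the ion channel gene Calhm5 by 4.40 ± 0.78. Btnl10 was at least 64.1-fold lower, Mageb16 at least 24.3-fold lower and Phyhip at least 16.9-fold lower. The red cell spectrin gene Sptb was at least 44.8-fold lower on its brighter probe set, and its other probe set read 0.37. Rhd, another red cell antigen gene, changed by -6.81 ± 0.55. The lower mean of Zfp365, Calhm5, Kel and Pax5 lay under its group's mean background, so the fitted changes are no exact sizes.

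Of 26 measured interferon-stimulated genes 23 rose and 0 fell (25 and 0 over the list alone), with a median of 1.81 and a mean of 1.89 ± 0.034 (adjusted p = 4.09e-22). Ifit3 rose by 3.28 ± 0.22 and Oasl2 by 3.03 ± 0.17. Of 38 measured p53 target genes 24 rose and 1 fell (27 and 1 over the list alone) at a median of 0.87 (adjusted p = 1.35e-11), with Ak1 at 2.93 ± 0.16 (another probe set 1.31). Mdm2 read 0.45 ± 0.12 on its brightest probe set and -0.56 to 0.88 over its probe sets, with adjusted p = 0.056 for their mean (range 1.82e-05 to 0.209). Of 26 measured NF-kB and cytokine genes 9 rose and 2 fell (9 and 2 over the list alone), at a median of 0.12 and adjusted p = 0.0187, but adjusted p = 0.11 with dim genes left out (range 8.91e-08 to 0.157). Cxcl10, an interferon-induced chemokine, rose by 2.78 ± 0.22.

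Genes of proliferation were lower than in the non-irradiated group. All 29 mitosis genes fell (29 over the list alone; median -1.72, adjusted p = 9.19e-24), with Cenpf at -2.53 ± 0.26 (another probe set -0.80) and Birc5 at -2.30 ± 0.14. Of 31 measured DNA replication genes 0 rose and 30 fell (0 and 31 over the list alone) at -1.75 (adjusted p = 2.89e-27), the cyclin Ccne1 by -3.00 ± 0.20. Of 20 measured homologous recombination and Fanconi genes 0 rose and 17 fell (0 and 17 over the list alone) at -1.78 (adjusted p = 6.58e-10), with Rad51ap1 at -2.95 ± 0.33. In the same arrays the erythroid mean change was -3.73 ± 0.079, the Gapdh 3' minus 5' signal was 0.77 ± 0.056 against 1.33 ± 0.040, and the hybridization controls were lower, at 12.42 ± 0.12 against 12.99 ± 0.063.

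Endothelial and matrix lists lay above the non-irradiated level. Of 29 measured pan-endothelial markers 13 rose and 0 fell (13 and 0 over the list alone) at a median of 0.40 (adjusted p = 3.86e-05), with Clec14a at 1.87 ± 0.32, Emcn at 1.31 ± 0.14 and Cdh5 at 0.63 ± 0.12. Pecam1 read 0.40 ± 0.18 (adjusted p = 0.096; 0.000686 when centred, range 0.000686 to 0.906). Of 14 measured sinusoidal endothelial markers 12 rose and 0 fell (12 and 0 over the list alone) at 0.86 (adjusted p = 2.64e-10), with the protease gene Adamts5 at 1.45 ± 0.17. Of 18 measured arterial and arteriolar endothelial markers 7 rose and 1 fell (7 and 1 over the list alone) at 0.44 (adjusted p = 0.0078), with Vegfc, a growth factor of lymphatic vessels, at 1.39 ± 0.12. Of 13 measured basement membrane genes 11 rose and 0 fell (11 and 0 over the list alone) at 1.24 (adjusted p = 2.61e-10), the laminin gene Lamb1 by 1.61 ± 0.12 (another probe set 0.78). Of 15 measured mesenchymal transition genes 11 rose and 1 fell (12 and 1 over the list alone) at 0.88 (adjusted p = 1.83e-08), where Tagln rose by 4.26 ± 0.28 and the protease gene Mmp2 by 1.69 ± 0.11. Of 18 measured stromal and osteoblast markers 13 rose and 2 fell (14 and 2 over the list alone) at 0.86 (adjusted p = 8.3e-09), the osteoblast factor Sp7 by 1.86 ± 0.15. With the erythroid covariate adjusted p was 0.294 for the pan-endothelial list (range 4.52e-11 to 0.294), 0.157 for the sinusoidal (2.84e-14 to 0.157), 0.605 for the arterial (1.16e-08 to 0.605), 0.35 for the mesenchymal (1.04e-14 to 0.35) and 0.166 for the stromal list (4.02e-12 to 0.166).

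Of the niche and angiocrine list 14 of 29 members rose and 1 fell (the same over the list alone; median 0.62, adjusted p = 2.66e-06). The lymphoid cytokine Il7 rose by 2.81 ± 0.23, Bmp4 by 2.06 ± 0.16 and Kitl by 0.62 ± 0.099. Cxcl12 read -0.28 ± 0.088 (adjusted p = 0.0182) on its brightest probe set, but 0.17 with quantile normalization, 0.11 when centred and 0.18 over its probe sets. Without 24-hour replicate 4 its adjusted p was 0.0752 (range 0.000383 to 0.926). Of 18 measured TGF-beta and BMP pathway genes 13 rose and 0 fell (16 and 0 over the list alone) at 0.98 (adjusted p = 1.41e-10), the inhibitory Smad6 by 3.28 ± 0.27. Of 20 measured VEGF and sprouting genes 12 rose and 1 fell (12 and 1 over the list alone) at 0.83 (adjusted p = 5.09e-07), Apln by 3.21 ± 0.45. Of 25 measured semaphorin, plexin and neuropilin genes 14 rose and 1 fell (14 and 1 over the list alone) at 0.62 (adjusted p = 5.77e-05). Of 16 measured coagulation and vessel-tone genes 11 rose and 0 fell (11 and 1 over the list alone) at 1.01 (adjusted p = 1.31e-06). Of 16 measured Notch pathway genes 5 rose and 0 fell (5 and 0 over the list alone) at 0.36, Lfng by 2.06 ± 0.17. The Notch list had adjusted p = 0.0075, or 0.0657 with dim genes left out (range 5.98e-09 to 0.87).

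Sterol biosynthesis genes rose in 9 of 16 cases and fell in 0 (the same alone; median 0.77, adjusted p = 0.000269), with the early pathway enzyme Hmgcs1 at 1.39 ± 0.16 (another probe set 0.27). Of 13 measured glycolysis genes 5 rose and 2 fell (6 and 2 over the list alone) at 0.42 with the glucose transporter Slc2a1 at 1.11 ± 0.19. The adjusted p was 0.0112, or 0.0737 with dim genes left out (range 2.77e-07 to 0.589). Of 7 measured control genes 0 rose and 4 fell (0 and 4 over the list alone) at -0.34 (0.042 with arrays centred on their medians). The adjusted p was 0.0205, 0.209 with an estimated correlation and 0.0538 without 24-hour replicate 4 (range 0.000606 to 0.853). Of 13 measured erythroid markers 0 rose and 12 fell (0 and 12 over the list alone), at a median of -4.24 (adjusted p = 2.12e-20). The anion exchanger Slc4a1 went from 12700 ± 399 to 287 ± 80 (-5.51 ± 0.20) and Rhag was at least 37-fold lower. Of 15 measured B-lineage markers 1 rose and 10 fell (2 and 11 over the list alone) at -1.54 (adjusted p = 0.00228, or 0.212 with dim genes left out, range 7.83e-07 to 0.668), with Pax5 at -3.35 ± 0.66 (another probe set -0.050). Ptprc read -0.33 ± 0.11 (adjusted p = 0.0227; 0.053 when centred). Its adjusted p was 0.0501 without 24-hour replicate 4, 0.058 without 24-hour replicate 3 and 0.0737 without non-irradiated replicate 3 (range 0.00379 to 0.812).

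At 24 hours the set test called 23 lists, 22 of them also with an estimated correlation, and 11 did not pass. Non-homologous end joining genes counted 0 higher and 1 lower of 10 (the same over the list alone), at a median of -0.17, above 0 with both other scalings (adjusted p = 0.536). Apoptosis genes counted 5 higher and 3 lower of 18 (8 and 3 over the list alone), at a median of 0.28 (adjusted p = 0.551). NRF2 and antioxidant genes counted 3 higher and 7 lower of 14 (4 and 7 over the list alone), at a median of -0.28, above 0 with both other scalings (adjusted p = 0.161). Senescence and secretory genes counted 4 higher and 2 lower of 16 (the same over the list alone), at a median of 0.074 (adjusted p = 0.106). Pan-leukocyte markers counted 0 higher and 4 lower of 15 (the same over the list alone), at a median of -0.020, above 0 with both other scalings (adjusted p = 0.262). Granulocyte markers counted 5 higher and 4 lower of 14 (6 and 4 over the list alone), at a median of 0.19 (adjusted p = 0.64). Monocyte and macrophage markers counted 4 higher and 5 lower of 17 (the same over the list alone), at a median of -0.21, above 0 with both other scalings (adjusted p = 0.441). T and NK cell markers had 1 higher and 2 lower of 14 (the same over the list alone), at a median of -0.33 (-0.25 with members at background set to their bounds), above 0 with both other scalings (adjusted p = 0.676). Megakaryocyte markers had 6 higher and 3 lower of 12 (the same over the list alone), at a median of 0.43 (adjusted p = 0.513). Stem and progenitor cell markers had 2 higher and 6 lower of 13 (3 and 6 over the list alone), at a median of -0.14, above 0 with both other scalings (adjusted p = 0.242). Mast cell and basophil markers had 0 higher and 2 lower of 6 (the same over the list alone), at a median of -0.74 (adjusted p = 0.199). The monocyte list had a mean of 0.042 with a downward test, and the megakaryocyte list a mean of -0.20 with an upward test. Under some alternatives lists passed: the senescence list had adjusted p = 0.0397 with quantile normalization, 0.0148 with the mean of a gene's probe sets and 0.0362 with the pan-leukocyte covariate (range 6.18e-09 to 0.176), and the granulocyte list 0.0238 with quantile normalization and 0.0235 when centred (range 0.0235 to 0.952). With the erythroid covariate 38 genes were higher and 41 lower.

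The comparison at day 14 asked which differences from non-irradiated cells were present then. Endothelial genes were lower: Cdh5 went from 3190 ± 494 to 1290 ± 270 (mean signal ± SD, n = 5 per group), a log2 change of -1.31 ± 0.12 (adjusted p = 2.66e-08). Pecam1 went from 1300 ± 228 to 426 ± 64.8 (-1.60 ± 0.18), and the endothelial transcription factor Sox17 from 900 ± 158 to 88.6 ± 29.8 (-3.37 ± 0.24). Interferon-stimulated genes were higher, and Mki67 read -0.37 ± 0.077, or 0.53 with arrays centred on their medians. Cdkn1a read 0.28 ± 0.096 (adjusted p = 0.0405), with another probe set at -0.17. Its adjusted p was 0.0959 with quantile normalization and from 0.0592 to 0.101 without day 14 replicate 2, 4 or 5 or non-irradiated replicate 1, 2 or 3 (range 9.29e-09 to 0.705). Mdm2 stood at -0.14 ± 0.12 (adjusted p = 0.436; 0.77 when centred), with probe sets from -2.22 to 0.34. Their mean read -0.67 (adjusted p = 2.62e-05, and range 2.62e-05 to 0.81).

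Over all genes 1723 were higher and 2359 lower (22.4%), and 215 and 1613 differed by at least 2-fold. The median of all genes was -0.18, against -0.022 at 6 hours and -0.073 at 24 hours. Quantile normalization moved it to 0.19 and the split to 1776 and 1139, and arrays centred on their medians gave 0.72 and 8212 and 461. Among genes above the median signal 1655 were higher and 1092 lower, and below it 68 and 1267. Without day 14 replicate 5, apart from its group in median signal, 1483 genes were higher and 2344 lower. Day 14 directions and sizes hold for the deposited scaling. Centring raised all changes alike: endothelial falls shrank or turned.

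Of 29 measured pan-endothelial markers 1 rose and 20 fell (1 and 23 over the list alone), with a median of -0.92 and a mean of -1.02 ± 0.033 (adjusted p = 4.42e-15). Nos3, the endothelial nitric oxide synthase gene, changed by -2.86 ± 0.32 and the growth factor receptor gene Flt1 by -2.13 ± 0.11. Of 18 measured arterial and arteriolar endothelial markers 2 rose and 7 fell (2 and 7 over the list alone), at a median of -0.71 (0.19 with arrays centred on their medians) and adjusted p = 0.0112, or 0.0918 when centred (range 7.34e-10 to 0.0918), with Podxl at -2.14 ± 0.21. Of 16 measured coagulation and vessel-tone genes 1 rose and 6 fell (1 and 6 over the list alone), at -0.19 (0.71 when centred). Their adjusted p was 0.00923, and 0.0943 with an estimated correlation (range 5.59e-07 to 0.743). The shear-stress factors Klf4 and Klf2 changed by -1.45 ± 0.084 and -1.44 ± 0.13. Of 13 measured basement membrane genes 1 rose and 5 fell (1 and 5 over the list alone), at -0.36 (0.54 when centred). Their adjusted p was 0.0326, 0.0585 with an estimated correlation, 0.0653 without day 14 replicate 5 and 0.0574 without non-irradiated replicate 1 (range 2.19e-06 to 0.159). Sinusoidal markers had 2 higher and 0 lower of 14 (the same alone; median -0.10, 0.80 when centred; adjusted p = 0.918). Alternatives called that list in opposite directions, downwards with quantile normalization (adjusted p = 0.0143) and upwards when centred (0.00138, range 0.00138 to 0.996).

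Of 26 measured interferon-stimulated genes 16 rose and 1 fell (19 and 1 over the list alone), at a median of 0.91 (adjusted p = 7.68e-14), with Ifit1 at 2.03 ± 0.22 and the guanylate-binding protein gene Gbp2 at 1.57 ± 0.21. Of 29 measured mitosis genes 11 rose and 1 fell (16 and 1 over the list alone), at a median of 0.49 (adjusted p = 6.73e-08), with the cyclin Ccnb2 at 0.98 ± 0.15. Of 31 measured DNA replication genes 9 rose and 1 fell (11 and 1 over the list alone), at 0.40 (adjusted p = 9.2e-06), with Rfc4 at 0.78 ± 0.16. Of 14 measured NRF2 and antioxidant genes 7 rose and 2 fell (7 and 2 over the list alone), at 0.27 (adjusted p = 0.00369), the haem-degrading Hmox1 by 1.26 ± 0.17. Of 16 measured sterol biosynthesis genes 6 rose and 0 fell (6 and 0 over the list alone), at 0.56 (adjusted p = 0.000164), Idi1 by 0.92 ± 0.20. Of 13 measured glycolysis genes 4 rose and 0 fell (5 and 0 over the list alone), at 0.28 with Tpi1 at 0.95 ± 0.18. Their adjusted p was 0.00369, or 0.288 with quantile normalization (range 1.67e-05 to 0.288). In these arrays the Gapdh 3' minus 5' signal was 0.89 ± 0.12 against 1.33 ± 0.040 and the pan-leukocyte mean change was -0.15 ± 0.031.

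Rises named by their fitted change were those of Hspa1a, a heat shock protein gene (2.49 ± 0.16), Rnf128 (2.54 ± 0.47), Fgf23 (2.54 ± 0.42), Nbl1 (at least 5.06-fold), the embryonic globin gene Hba-x (at least 1.78-fold) and Des (2.63 ± 0.60), whose other probe set read -2.43. Usp53 (-4.42 ± 0.68; another probe set -0.80), Insyn2b (-4.31 ± 0.77), Ccdc85a (at least 10.4-fold lower; another probe set -1.87), Adgb (at least 4.46-fold), Ttll7 (-3.71 ± 0.48) and Gpr17 (at least 3.58-fold) were the falls so named. Bounds give no rank, and the lower mean of Fgf23, Des, Insyn2b and Ttll7 lay under its group's mean background. Of 13 measured erythroid markers 2 rose and 0 fell (2 and 0 over the list alone), at a median of 0.31. Their adjusted p was 0.0351, 0.133 with an estimated correlation, 0.299 with quantile normalization, 0.0783 without day 14 replicate 1, and 0.0531 without non-irradiated replicate 1 or 2 (range 0.0013 to 0.299). The haem synthesis gene Alas2 rose by 1.25 ± 0.13. Of 14 measured granulocyte markers 2 rose and 7 fell (4 and 9 over the list alone), at -0.32 (0.58 when centred). Their adjusted p was 0.0351, 0.257 with an estimated correlation, 0.0816 without day 14 replicate 5, and 0.0804 and 0.0536 without non-irradiated replicates 4 and 5 (range 9.7e-05 to 0.257). Ptprc changed by -0.81 ± 0.11 (0.089 when centred) and Cxcl12 by -0.39 ± 0.088 (0.51 when centred). Cxcl12 read -0.019 with quantile normalization (adjusted p = 0.764), and its adjusted p was 0.0613 with the pan-leukocyte covariate (range 0.000316 to 0.764). Kitl read 0.0080 ± 0.099 (adjusted p = 0.966; 0.91 when centred).

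Of the 34 lists 12 were called at day 14 and 8 of them also with an estimated correlation. The coagulation, basement membrane, erythroid and granulocyte lists were lost. Among the lists of damage and stress responses 6 did not pass. P53 target genes had 7 higher and 6 lower of 38 (9 and 7 over the list alone), at a median of 0.13 (adjusted p = 0.125). Homologous recombination and Fanconi genes had 1 higher and 1 lower of 20 (the same over the list alone), at a median of 0.12 (adjusted p = 0.234). Non-homologous end joining genes had 0 higher and 0 lower of 10 (the same over the list alone), at a median of -0.14, above 0 with both other scalings (adjusted p = 0.646). Apoptosis genes had 4 higher and 3 lower of 18 (5 and 5 over the list alone), at a median of -0.060, above 0 with both other scalings (adjusted p = 0.415). NF-kB and cytokine genes had 4 higher and 9 lower of 26 (5 and 9 over the list alone), at a median of -0.29, above 0 with both other scalings (adjusted p = 0.327). Senescence and secretory genes had 4 higher and 1 lower of 16 (the same over the list alone), at a median of 0.069 (adjusted p = 0.234). For 8 of the 22 lists without a call median, mean and test direction did not share a sign. The p53 list, for example, had a mean of -0.055 with an upward test and the niche list a mean of -0.19 with an upward test. No called list at any of the 3 times had such a difference. Past the threshold in an alternative were the p53 list at 0.0157 when centred and 0.0449 with the pan-leukocyte covariate (range 0.0157 to 0.613), the apoptosis list at 0.0297 when centred (range 0.0297 to 0.979) and the senescence list at 0.0157 with the mean of a gene's probe sets (range 0.0157 to 0.468).

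Signalling and stromal lists did not pass either in the deposited scaling with all arrays, though some did under alternatives. Niche and angiocrine factors counted 2 higher and 5 lower of 29 (the same over the list alone), at a median of 0.0077 (adjusted p = 0.918). Semaphorin, plexin and neuropilin genes counted 1 higher and 7 lower of 25 (the same over the list alone), at a median of -0.27, above 0 with both other scalings (adjusted p = 0.125). VEGF and sprouting genes counted 1 higher and 6 lower of 20 (2 and 8 over the list alone), at a median of -0.16, above 0 when centred (adjusted p = 0.0633). Notch pathway genes counted 1 higher and 7 lower of 16 (2 and 7 over the list alone), at a median of -0.28, above 0 when centred (adjusted p = 0.151). TGF-beta and BMP pathway genes counted 2 higher and 3 lower of 18 (the same over the list alone), at a median of 0.049 (adjusted p = 0.475). Mesenchymal transition genes counted 2 higher and 4 lower of 15 (the same over the list alone), at a median of -0.093 (-0.038 with members at background set to their bounds), above 0 when centred (adjusted p = 0.44). Stromal and osteoblast markers counted 6 higher and 5 lower of 18 (6 and 6 over the list alone), at a median of -0.0027, above 0 when centred (adjusted p = 0.62). Without day 14 replicate 1, 3 or 4 the VEGF list had adjusted p = 0.0475, 0.0472 and 0.0463 and elsewhere 6.66e-05 with quantile normalization and 0.0137 with dim genes left out (range 9.38e-10 to 0.304). Semaphorin genes reached 0.0321 with dim genes left out and 0.013 with the mean of a gene's probe sets (range 8.61e-07 to 0.902) and Notch genes 0.0307 with dim genes left out (range 9.5e-06 to 0.808), both downwards. Adjusted p of TGF-beta genes was 0.0134 when centred (range 0.0134 to 0.981) and that of stromal markers 0.000275 when centred (range 0.000275 to 0.931), both upwards. Mesenchymal genes passed downwards and upwards in turn, at 0.0356 with quantile normalization and 0.0441 when centred (range 0.00102 to 0.656).

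Control genes and the remaining lists of other cells also did not pass. Control genes numbered 1 higher and 2 lower of 7 (the same over the list alone), at a median of 0.024 (adjusted p = 0.993). Pan-leukocyte markers numbered 1 higher and 5 lower of 15 (1 and 6 over the list alone), at a median of -0.13, above 0 when centred (adjusted p = 0.125). Monocyte and macrophage markers numbered 1 higher and 4 lower of 17 (1 and 5 over the list alone), at a median of -0.44, above 0 when centred (adjusted p = 0.0685). B-lineage markers numbered 0 higher and 2 lower of 15 (the same over the list alone), at a median of -0.45, above 0 with both other scalings (adjusted p = 0.364). T and NK cell markers numbered 1 higher and 1 lower of 14 (the same over the list alone), at a median of -0.57, above 0 with both other scalings (adjusted p = 0.551). Megakaryocyte markers numbered 3 higher and 4 lower of 12 (the same over the list alone), at a median of -0.25, above 0 when centred (adjusted p = 0.596). Stem and progenitor cell markers numbered 0 higher and 3 lower of 13 (the same over the list alone), at a median of -0.53, above 0 when centred (adjusted p = 0.063). Mast cell and basophil markers numbered 0 higher and 2 lower of 6 (the same over the list alone), at a median of -0.71 (-0.46 with members at background set to their bounds), above 0 when centred (adjusted p = 0.0881). The monocyte list had adjusted p = 0.0359 without non-irradiated replicate 2, and 0.00759 with quantile normalization, 0.00287 with dim genes left out, 0.0455 with array weights, 0.0322 with the pan-leukocyte covariate and 0.0463 with the erythroid covariate (range 0.000836 to 0.931). For the stem and progenitor list it was 0.0469 and 0.0477 without day 14 replicates 3 and 5, and 0.0156 with quantile normalization and 0.0443 with array weights (range 5.79e-05 to 0.428). Control genes passed upwards at 0.00471 when centred (range 0.00471 to 0.996). Pan-leukocyte markers passed at 1.78e-05 with quantile normalization, 0.0351 when centred and 0.0381 with dim genes left out (range 1.2e-05 to 0.72), upwards when centred and downwards otherwise.

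**Figure D2:**
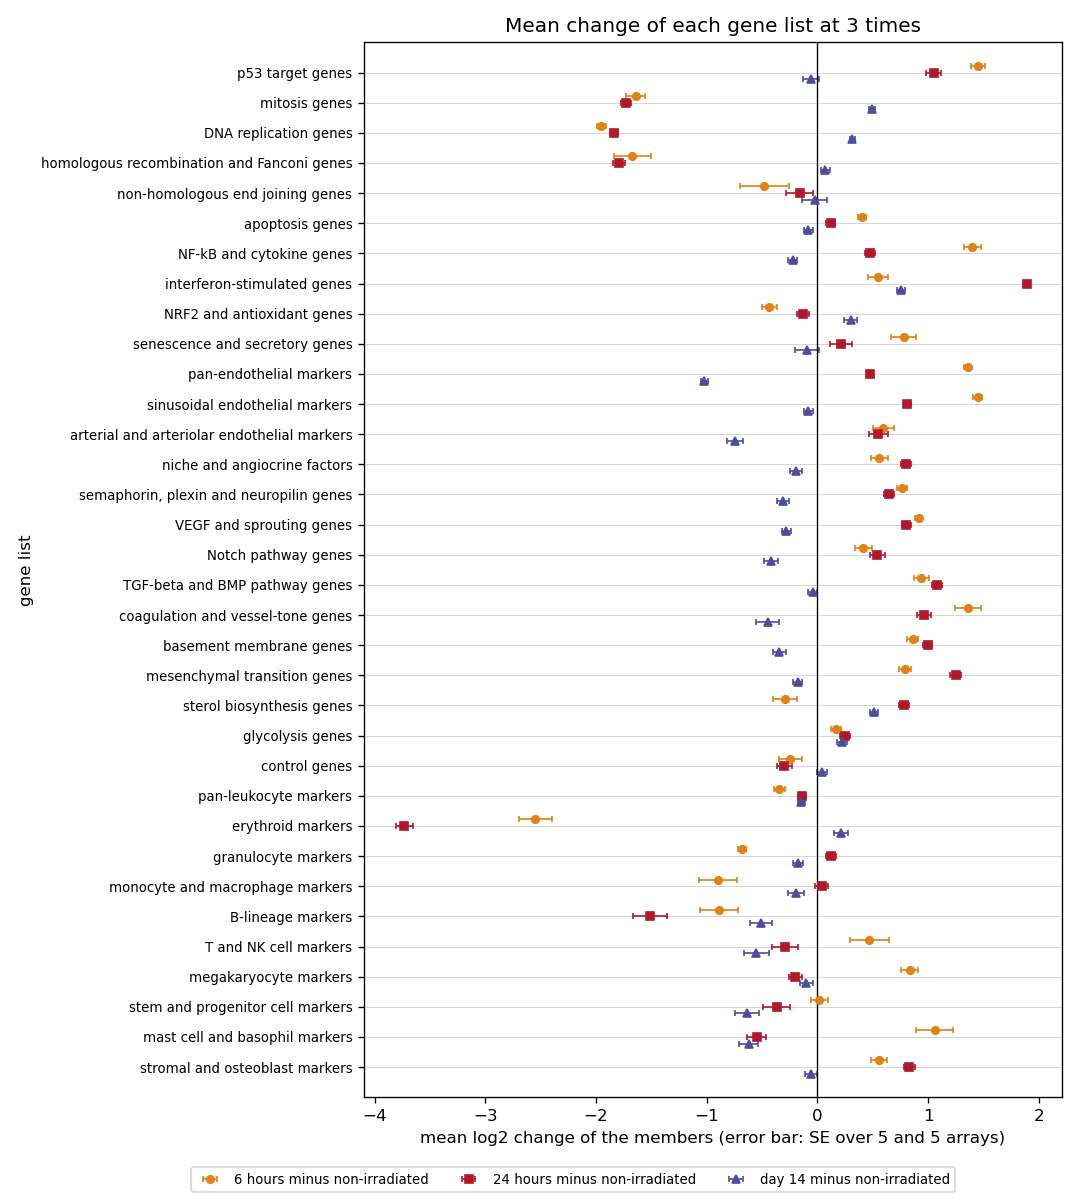
Mean log2 change against non-irradiated of the measured members of 34 gene lists at 6 hours (circles), 24 hours (squares) and day 14 (triangles), with the SE over 5 and 5 arrays as bars. Pan-endothelial markers stood at 1.36, 0.47 and -1.02 and mitosis genes at -1.64, -1.73 and 0.49; with arrays centred on their medians the medians of 20 lists change sign at day 14.

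Direct contrasts asked whether the irradiated groups differed from each other. Between 6 and 24 hours 2493 genes were higher at 24 hours and 1831 lower (3150 and 1231 with arrays centred on their medians). Of 26 measured interferon-stimulated genes 22 rose and 0 fell (23 and 0 over the list alone), with a mean difference of 1.35 ± 0.084 (adjusted p = 1.72e-18). Of 16 measured sterol biosynthesis genes 11 rose and 0 fell (13 and 0 over the list alone) (1.07 ± 0.11, adjusted p = 1.2e-07). Of 29 measured pan-endothelial markers 0 rose and 24 fell (0 and 25 over the list alone) (-0.89 ± 0.028, adjusted p = 9.42e-17). Of 38 measured p53 target genes 3 rose and 14 fell (3 and 19 over the list alone) (-0.40 ± 0.026, adjusted p = 0.000129). Of 26 measured NF-kB and cytokine genes 4 rose and 15 fell (4 and 15 over the list alone) (-0.92 ± 0.073, adjusted p = 1.2e-07). Adtrp was at least 4.45-fold higher at 24 hours, Sfrp2, a secreted Wnt antagonist, rose by 5.38 ± 0.57, Actg2 by 5.20 ± 0.70 and Mgam by 5.10 ± 0.72. Fgf23 changed by -4.03 ± 0.42, Vwa3a was at least 6.2-fold lower (another probe set 1.17), Sowaha at least 5.96-fold lower, and Igkv6-14 read an uncertain -5.01 ± 0.37. The 6-hour means of Sfrp2 and Actg2 lay under that group's mean background.

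Between 24 hours and day 14 2765 genes were higher at day 14 and 3944 lower (4972 and 1687 when centred). All 29 mitosis genes rose, by a mean of 2.23 ± 0.045 (adjusted p = 6.42e-30). Of 13 measured erythroid markers 12 rose and 0 fell (12 and 0 over the list alone), by a mean of 3.94 ± 0.084 (adjusted p = 1.85e-20). Of 29 measured pan-endothelial markers 0 rose and 27 fell (0 and 28 over the list alone) (-1.49 ± 0.030, adjusted p = 2.24e-17). Of 26 measured interferon-stimulated genes 1 rose and 18 fell (1 and 19 over the list alone) (-1.14 ± 0.024, adjusted p = 3.65e-07). Btnl10 was at least 89.6-fold higher at day 14, Sptb at least 81.7-fold higher (another probe set -0.57), and Fn3k and Rhd rose by 7.85 ± 0.57 and 7.84 ± 0.55. Acta2 changed by -5.59 ± 0.28 (another probe set -1.14), Actg2 was at least 11.7-fold lower, Slc22a14 at least 11.4-fold lower, and Igkv15-103 read an uncertain -4.62 ± 0.30. The 24-hour mean of Fn3k lay under its group's mean background.

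Between 6 hours and day 14 3611 genes were higher at day 14 and 4553 lower, against 4028 and 2873 with quantile normalization and 6652 and 1755 when centred. Of 29 measured pan-endothelial markers 0 rose and 28 fell (0 and 28 over the list alone) (-2.37 ± 0.035, adjusted p = 1.61e-24). Of 38 measured p53 target genes 0 rose and 31 fell (0 and 31 over the list alone) (-1.50 ± 0.040, adjusted p = 3.22e-12). All 29 mitosis genes rose (2.13 ± 0.085, adjusted p = 3.33e-23). The carbonic anhydrase gene Car4 changed by -5.32 ± 0.41, Tlcd3b by -6.17 ± 0.56 (another probe set -1.54), Ttll7 by -4.87 ± 0.48 and Vsig2 by -4.84 ± 0.37. Fn3k was at least 41.2-fold higher, the tachykinin gene Tac2 at least 38.7-fold higher, and Rhd and Btnl10 rose by 6.87 ± 0.55 and 6.78 ± 0.53. The lower means of Tlcd3b, Ttll7 and Btnl10 lay under their groups' mean background. An F test over all 4 groups called 10032 genes (55.1%). With the 3' minus 5' covariate 5098 genes differed between 6 hours and day 14 and 1891 between 6 and 24 hours.

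**Figure D3:**
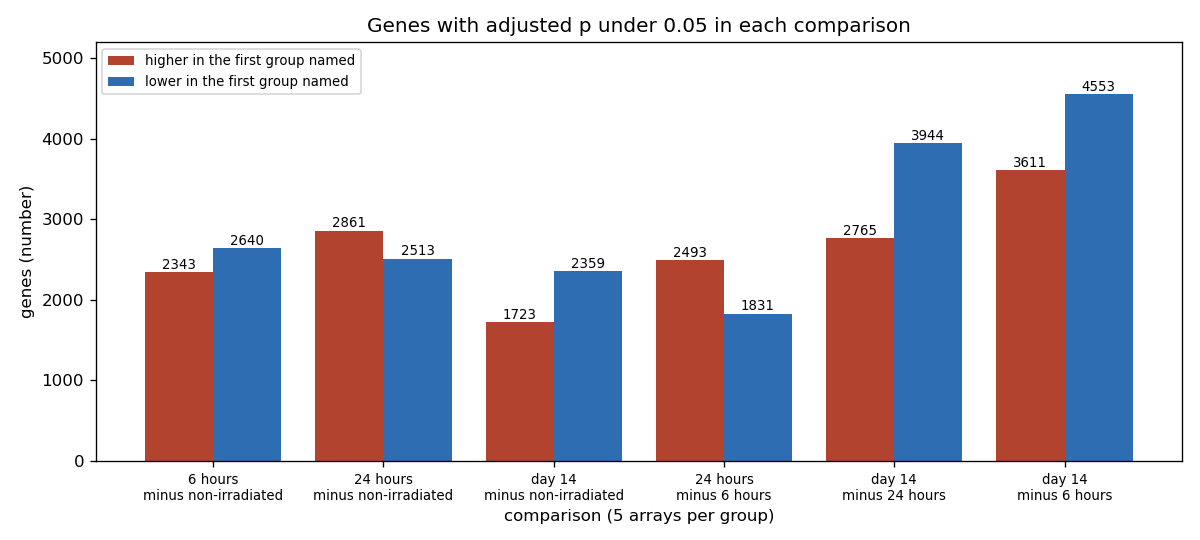
Number of genes with adjusted p under 0.05 in each of the 6 comparisons of 2 groups of 5 arrays, higher (red) or lower (blue) in the group named first. The counts run from 1723 higher at day 14 against non-irradiated to 4553 lower at day 14 against 6 hours, in the deposited scaling; with arrays centred on their medians more genes are higher than lower in every comparison.

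As the 3 times share controls, overlaps stand beside the count expected of independent lists and that with controls split so that none is shared. At 6 and 24 hours 1417 genes were higher and 1424 lower in both. The counts were 368.5 and 364.7 expected of independent lists and 926 and 933 with split controls. Calls in opposite directions numbered 147. At 6 hours and day 14 316 and 291 were shared (expected 221.9 and 342.3; split controls 140.5 and 110.5) and 1030 were opposite. At 24 hours and day 14 the shared genes were 574 and 557 (expected 271 and 325.8; split controls 287 and 212) and 587 were opposite. Unchanged groups simulated 50 times against the same controls shared 0 calls. The correlation of log2 changes across genes was 0.579 between 6 and 24 hours, 0.0528 between 6 hours and day 14 and 0.322 between 24 hours and day 14, against 0.499, 0.499 and 0.501 in the simulations. The covariances were 0.488, 0.0378 and 0.24, against a simulated 0.109. Genes are not independent replicates, so no p is given.

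Every called list and all but 7 of 324 called named changes had all 5 irradiated arrays on the side of the change. The naming rule and the calls largely fixed this. The 7 (4 of 5 arrays) were Prkdc, Slc7a11, Dhcr7, Tbp, Hprt, Vpreb1 and Gfi1 at 6 hours. The arrays of a comparison were fully separated for 2846 genes (15.6%) at 6 hours, 5095 (28%) at 24 hours and 4179 (23%) at day 14, where chance gives 0.794%.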

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

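Of the tests reported in this part, those of the scaling at day 14, of erythroid loss against the endothelial and erythroid pattern, and of the 3' minus 5' signal against the proliferation genes at both times were chosen after the result was seen. All patterns were found and tested on the same arrays.

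At day 14 more genes were lower than higher, 1.37 lower calls per higher call. With the 3' minus 5' signal as a covariate the ratio was 1.38 (1337 higher and 1850 lower). Of that signal's variance 76.4% lay between groups, so amplification quality as the cause stays open. With quantile normalization the ratio was 0.641 (1776 higher and 1139 lower), and with arrays centred on their medians 0.0561. The scaling of the arrays may therefore account for the excess of lower calls. A lower amount of RNA of many dim genes after irradiation stays open and was not tested.

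At 6 hours pan-endothelial markers rose while erythroid markers fell, and the erythroid gene Klf1 read 5690 ± 288 in non-irradiated arrays, although a sort on VE-cadherin would remove erythroid cells. A loss of erythroid RNA alone would raise all other RNA alike, but the pan-endothelial and pan-leukocyte means moved apart by 1.70 ± 0.051, which argues against it as the whole cause. A larger share of endothelial RNA of unchanged make-up would raise endothelial subtypes alike. The 14 sinusoidal markers well above background rose by a mean of 1.45 ± 0.041 and the 11 arterial ones by 0.67 ± 0.072. The difference was 0.784 ± 0.0913. This decides nothing, as the error omits spread between genes and other cells may share markers. Both may contribute in part. A response of the endothelial cells to irradiation stays open, since no test here separates it from changes in which cells were sorted.

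Mitosis and DNA replication genes were lower at 6 and 24 hours. The 3' minus 5' signal differed from the non-irradiated arrays by -0.23 ± 0.028 at 24 hours. With it as a covariate the mean mitosis shift was -1.57 ± 0.081 against -1.73 ± 0.046. The DNA replication shift was -1.87 ± 0.048 against -1.84 ± 0.036. This argues against a linear effect of that signal as the whole cause at that time. As 76.4% of its variance lay between groups, other effects of amplification quality stay open. At 6 hours the signal differed by 0.13 ± 0.074. The median mitosis shift of -1.75 beside it, against -1.69, could therefore hardly have moved and decides nothing. From the slope within groups on the erythroid mean (0.042 ± 0.14), the erythroid shift at 6 hours predicted a mitosis shift of -0.107 ± 0.38, short of the -1.64 ± 0.085 seen. That bound was set too firmly beforehand, because the erythroid mean varied within groups by an SD of 0.19 with a reliability of 0.534, and 99% of its variance lay between groups. A loss of cycling erythroid precursors and fewer cycling endothelial cells therefore cannot be told apart.

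Random regroupings of the same arrays, 100 splits per result with the real split included, asked whether chance can be excluded. Chance can be excluded for the counts of changed genes, where only 1 of 100 splits, the real one, gave as many: 4983 at 6 hours (highest other 776), 5374 at 24 hours (10), 4082 at day 14 (6), 4324 between 6 and 24 hours (320), 6709 between 24 hours and day 14 (2), 8164 between 6 hours and day 14 (2488) and 10032 among the 4 groups (241). Genes called in 1 direction at 2 times numbered 2841 at 6 and 24 hours (highest other 3), 607 at 6 hours and day 14 (2) and 1131 at 24 hours and day 14 (0), but regrouped arrays mix the groups and leave few calls to share. These splits therefore do not show that more genes were shared than separate changes would share by chance. At 6 hours and day 14 316 higher and 291 lower genes were shared, beside 221.9 and 342.3 expected of independent lists. The number of lists called was reached by other splits too. At 6 hours 3 of 100 reached the real 26 (highest other 26) and at 24 hours 4 the 23 (23). At day 14 5 reached the 9 (10). Chance is therefore not excluded for these counts. Each time was adjusted alone in these counts of lists, so the day 14 count differs from the 12 of the 102 tests together.

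In 336 groups of 5 arrays the gap of the highest or lowest array to its neighbour, divided by the group's range, was above 0.71 in 22 cases, and chance gives about 1 in 20, or 16.8. Replicate 5 of day 14 stood apart in its median signal (ratio 0.721; 109 against 87.3 to 93.3) and on the first and the next principal component (ratios 0.891 and 0.791). Non-irradiated replicate 1 stood apart in the Actb 3' minus 5' log2 signal (ratio 0.773; -0.034 against -0.13 to -0.11) and in the log2 signal of the B2 repeat (ratio 0.756; 14.57 against 14.81 to 14.89). List means on the log2 scale stood apart for NF-kB and cytokine genes in 24-hour replicate 3 (ratio 0.806; 9.30 against 9.13 to 9.17), interferon-stimulated genes in 6-hour replicate 5 (ratio 0.749; 8.96 against 9.32 to 9.44), pan-endothelial markers in 6-hour replicate 2 (ratio 0.792; 11.35 against 11.22 to 11.25), sterol biosynthesis genes in 24-hour replicate 5 (ratio 0.721; 9.56 against 9.72 to 9.79) and erythroid markers in day 14 replicate 1 (ratio 0.871; 12.08 against 11.81 to 11.85).

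Single genes with an array far from its group, as log2 signals, were Fgf23 in non-irradiated replicate 4 (ratio 0.745; 2.42 against 4.52 to 5.23), Btnl10 in non-irradiated replicate 1 (ratio 0.943; 10.68 against 10.80 to 10.80), Cdkn1a in 6-hour replicate 2 (ratio 0.81; 12.35 against 12.56 to 12.61) and Ptprc in 24-hour replicate 1 (ratio 0.792; 12.14 against 11.79 to 11.86). Of the smooth muscle and channel genes, this was so for Actg2 in 6-hour replicate 5 (ratio 0.719; 6.50 against 0.98 to 2.53) and for Calhm5 in 6-hour replicate 4 (ratio 0.763; 2.24 against 6.38 to 7.67) and in day 14 replicate 5 (ratio 0.751; 4.44 against 6.02 to 6.55). The others were Kel in 24-hour replicate 4 (ratio 0.767; 1.01 against 4.57 to 5.65), Phyhip in non-irradiated replicate 5 (ratio 0.844; 9.68 against 8.53 to 8.71), Nbl1 in 6-hour replicate 4 (ratio 0.862; 4.36 against 7.36 to 7.84), Hspa1a in 24-hour replicate 1 (ratio 0.751; 9.43 against 8.73 to 8.90) and Ccdc85a in day 14 replicate 4 (ratio 0.778; 4.30 against 3.93 to 4.01).

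Effects against the same non-irradiated arrays differed between times by the direct test in 4324 genes for 24 against 6 hours, 6709 for day 14 against 24 hours and 8164 for day 14 against 6 hours. List shifts called with opposite signs at 2 times were tested the same way. For day 14 minus 24 hours the mean log2 differences were 2.23 ± 0.045 (adjusted p = 6.42e-30) for mitosis genes, 2.15 ± 0.031 (adjusted p = 2.88e-30) for DNA replication genes and 3.94 ± 0.084 (adjusted p = 1.85e-20) for erythroid markers. They were -1.49 ± 0.030 (adjusted p = 2.24e-17) for pan-endothelial markers, -1.30 ± 0.056 (adjusted p = 9.35e-06) for arterial markers, -1.41 ± 0.087 (adjusted p = 6.94e-10) for coagulation genes and -1.34 ± 0.044 (adjusted p = 2.08e-11) for basement membrane genes. For day 14 minus 6 hours they were 2.13 ± 0.085 (adjusted p = 3.33e-23) for mitosis genes, 2.27 ± 0.032 (adjusted p = 1.96e-26) for DNA replication genes, 0.74 ± 0.067 (adjusted p = 0.00059) for NRF2 genes and 2.76 ± 0.15 (adjusted p = 6.7e-14) for erythroid markers. The endothelial, arterial, coagulation and basement membrane lists read -2.37 ± 0.035 (adjusted p = 1.61e-24), -1.34 ± 0.069 (adjusted p = 0.00116), -1.80 ± 0.13 (adjusted p = 5.57e-10) and -1.20 ± 0.052 (adjusted p = 1.03e-08). Some of the calls against non-irradiated arrays behind these signs are lost with an estimated correlation: at day 14 the coagulation (0.0943; range 5.59e-07 to 0.743), basement membrane (0.0585; 2.19e-06 to 0.159) and erythroid lists (0.133; 0.0013 to 0.299), and at 6 hours the NRF2 list (0.0682; 4.21e-08 to 0.244). When centred, the day 14 medians of the arterial, coagulation and basement membrane lists were positive (0.19, 0.71 and 0.54).

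Of 10092 probe sets with no single gene name, 1857 changed against non-irradiated arrays at 6 hours (445 higher and 1412 lower). At 24 hours 2662 did (383 and 2279) and at day 14 4512 (278 and 4234).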

How the results depend on the processing

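Alternatives added after seeing the data are named above. Where a value changed, the cause was not tested, except that a stricter threshold makes fewer calls. With 5 arrays per group, signal near background limits what can be called, as the recovered shares of the simulated data show. Counts of genes stayed within 1.5 times of the reported ones with no intensity trend, with 16 added and without probe sets open to cross-hybridization. Of 102 list shifts 61 were called, 55 with an estimated correlation, 66 with quantile normalization, 65 when centred, 59 with dim genes left out, 64 with the mean of a gene's probe sets, 63 with array weights, 56 with the 3' minus 5' covariate, 59 with the pan-leukocyte covariate and 61 with 16 added. Fry called 87. With the erythroid covariate 35 were called.

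Leaving out 1 array at a time, the counts ranged as follows: 2147 to 2378 higher, 2418 to 2763 lower at 6 hours, 2598 to 2708 higher, 2194 to 2329 lower at 24 hours, 1336 to 1529 higher, 1813 to 2344 lower at day 14. Between 6 and 24 hours 3658 to 4436 genes differed, between 24 hours and day 14 6120 to 6486, between 6 hours and day 14 7350 to 8241 and among the 4 groups 9411 to 10278. The list shifts called ranged from 59 to 63. With 1 array left out 143 named-gene comparisons lost their call and 1 gained it, and 9 and 6 list shifts did.

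With arrays centred on their medians the counts were 3532 higher and 1617 lower at 6 hours, 4950 and 1139 at 24 hours and 8212 and 461 at day 14. Every probe set gave 4209 higher and 6713 lower at 6 hours, 5192 and 7488 at 24 hours and 3299 and 10389 at day 14, with 8848 between 6 and 24 hours, 14687 between 24 hours and day 14, 19069 between 6 hours and day 14 and 24592 among the 4 groups. A 2-fold minimum gave 1139 higher and 1419 lower at 6 hours, 1464 and 1338 at 24 hours and 215 and 1613 at day 14. It gave 2068, 3879, 5309 and 5630 for the other contrasts in the same order, and shared calls (higher and lower) of 458 and 716 for 6 and 24 hours, 42 and 154 for 6 hours and day 14 and 76 and 278 for 24 hours and day 14. With the controls split, the shared calls were 926 and 933, 140.5 and 110.5 and 287 and 212. An adjusted p under 0.01 gave 919 higher and 1233 lower at day 14 and 2713 between 6 and 24 hours. Array weights gave 2685 higher and 3557 lower at day 14, and a fit of the 2 groups only 2909 higher. Lower calls at day 14 numbered 1139 with quantile normalization, 1521 with dim genes left out and 3624 with the mean of a gene's probe sets.

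The pan-leukocyte covariate gave 509 higher and 525 lower at 6 hours, 919 and 1257 at day 14, 1609 between 6 and 24 hours and 4368 between 6 hours and day 14. The 3' minus 5' covariate gave 1891 between 6 and 24 hours and 5098 between 6 hours and day 14. With the erythroid covariate 47 genes were higher and 95 lower at 6 hours and 38 and 41 at 24 hours, and 912, 63 and 274 genes differed in the direct contrasts, while at day 14 1560 were higher and 2042 lower. Of 330 named changes (324 past the threshold) 229 lost their call with it, 42 of them turned. As 99% of its variance lay between groups, the turned values (adjusted p over 0.2) show no reversal. The turned log2 values were, Rhd 2.51, Palb2 0.63, Xrcc6 1.54, Xrcc5 1.03, Pmaip1 -0.47, Slc7a11 2.93, Gclc 0.012, Bmx 5.62, Sema3g -0.58, Dll4 -0.97, Dhcr7 0.080, Tbp 2.13, Hprt 1.33, Elane 0.20, Vpreb1 3.99, Gfi1 3.59 at 6 hours and Actg2 -4.94, Zfp365 -0.30, Calhm5 -6.78, Mx2 -0.76, Rhd 5.43, Cdc25c 0.81, Bard1 0.12, Xrcc6 3.97, Pmaip1 -2.65, Stab1 -1.31, Gpm6a -2.03, Hey1 -0.41, Sema3f -2.91, F3 -3.78, Sc5d -1.54, Msmo1 -2.18, Slc2a1 -0.43, Hprt 2.25, Sdha 0.87, Rhag 0.55, Fcnb -3.16, Vpreb1 7.28, Klrd1 0.79, Cd2 2.12, Mcpt8 0.36, Cdh5 -0.097 at 24 hours. With the pan-leukocyte covariate 90 lost it, with quantile normalization 26 and with the mean of a gene's probe sets 25. List shifts that lost it with the erythroid covariate were, at 6 hours homologous recombination, interferon-stimulated, NRF2, arterial, Notch, mesenchymal, pan-leukocyte, erythroid, granulocyte, monocyte, stromal; at 24 hours homologous recombination, NF-kB, pan-endothelial, sinusoidal, arterial, semaphorin, Notch, coagulation, mesenchymal, sterol, glycolysis, control, erythroid, B-lineage, stromal; at day 14 erythroid.

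With median centring 28 named changes turned direction, and 42 lost their call, 17 of them turned. The turned values were Sdha 0.037, Ptprc 0.053, Cxcl12 0.11 at 24 hours and Rad54l 0.10, Id1 0.0050, Skil 0.14, Hspg2 0.10, Sparc 0.53, S100a4 0.35, Fn1 0.42, Vim 0.51, Actb 0.49, Ywhaz 0.70, Ptprc 0.089, Cd53 0.21, Itgb2 0.34, S100a8 0.19, Csf1r 0.078, Tyrobp 0.32, Ighm 0.11, Itga2b 0.20, Clec1b 0.22, Cd34 0.33, Gata2 0.48, Hdc 0.024, Mdm2 0.77, Mki67 0.53, Cxcl12 0.51 at day 14. With quantile normalization the turned values were Cxcl12 0.17 at 24 hours and Sparc 0.023, Actb 0.024 at day 14. With the mean of a gene's probe sets they were at 6 hours Fdps 0.43; at 24 hours Cxcl12 0.18; at day 14 Aurka -0.0020, Ctsl -0.49, Fdft1 -0.24, and with 16 added Orc1 0.39 at day 14. List shifts whose test direction turned had medians, when centred, of basement membrane genes 0.54, mesenchymal transition genes 0.81, pan-leukocyte markers 0.77, granulocyte markers 0.58 at day 14. With quantile normalization this was sinusoidal endothelial markers -0.13 at day 14, with fry megakaryocyte markers 0.43 at 24 hours and niche and angiocrine factors 0.0077 at day 14, and with the erythroid covariate control genes 0.092, B-lineage markers -0.14 at 24 hours.

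With the replicate number as a replicate block, all counts stayed within 1.5 times of the reported ones, from 1653 higher at day 14 to 9838 among the 4 groups, and 61 list shifts were called. The block ended the calls of Dll4 at 6 hours, Meis1 at 24 hours and Cdkn1a at day 14 (adjusted p = 0.06) and changed no other call of a named gene or list. The deviations of same-numbered arrays from their group means had correlations across genes of -0.0665 to 0.0493 over 30 pairs, and 4 of 20 arrays correlated best with an array of their own number, which gives no sign that same-numbered arrays are paired.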

Other observations

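Between 6 and 24 hours granulocyte and monocyte markers rose, while megakaryocyte markers fell. The lists described here were chosen after their values were seen, and genes are the 2 called members that moved furthest with the list. Granulocyte markers had 12 higher and 2 lower of 14 (12 and 2 adjusted over the list alone; mean difference 0.80 ± 0.036; adjusted p = 2.15e-09), led by Fcnb (2.07 ± 0.19) and Elane (1.72 ± 0.17). Of the monocyte and macrophage markers, the counts were 7 higher and 2 lower of 17 (11 and 3 over the list alone; mean difference 0.94 ± 0.17; adjusted p = 0.000245), the furthest near background at 6 hours and not given. Megakaryocyte markers went down, 0 higher and 9 lower of 12 (0 and 10 over the list alone; mean difference -1.03 ± 0.064; adjusted p = 1.81e-10), as in Gfi1b (-1.74 ± 0.15) and Gp5 (-1.43 ± 0.35). Between the same groups the Gapdh 3' minus 5' log2 signal went from 1.58 ± 0.29 to 0.77 ± 0.056 and the hybridization controls from 13.08 ± 0.15 to 12.42 ± 0.12 (SD). With the 3' minus 5' signal as a covariate 1891 genes differed in place of 4324, and these lists were not tested again beside it.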
